A study of Mus musculus with 2 samples.

How the data were processed

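Single-cell RNA sequencing was carried out with the 10x Chromium 3′ chemistry on cells from MC38 tumours, a mouse colon carcinoma line grown in C57BL/6 albino mice. Per the labels' protocols, tumours were dissociated, the fraction of 40 to 100 µm was embedded in collagen and cultured in a microfluidic chip, and the cultures received antibody at 10 µg/mL. On day 6 the spheroids were digested with collagenase and trypsin, and tumour cells were isolated by flow cytometry before loading. The markers used for that sort are not given in the sources used here. The treatments were a control IgG and an antibody that blocks PD-1, the inhibitory receptor of T cells (aPD-1), with 1 library each.

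The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger 3.0.2 per the file headers and not normalised. The submitters' processing notes name Cell Ranger, the mouse build mm10 and Seurat 2.1.0, and the gene annotation is not given in the sources used here. Both matrices list the same 28692 genes. The IgG matrix held 4351 barcodes, none under 500 UMIs, so it had been reduced to called cells, whereas the aPD-1 matrix held all 737280 possible barcodes, of which 523832 had a UMI. Of the aPD-1 UMIs, 7.20% lay in barcodes under 500 UMIs, and the IgG library has no such barcodes to compare. Cells were therefore called in the aPD-1 library alone by an order-of-magnitude rule (1/10 of the 99th percentile of the top 3000 barcodes), which set a floor of 4592 UMIs. The same filters were then applied to both libraries: at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. These filters were fixed before the data were examined, as were the gene lists, the tests and the rule for naming genes. The floors differed between the libraries, so shares of shallow cells are set in part by them.

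Doublets were called with scrublet in scanpy 1.11.5. It marked 9 of 5826 cells (0.154%), too few for a working caller, so no doublet was removed and doublets remain in the sums. Both libraries were clustered together without integration in scanpy, on log counts per 10000, 2000 variable genes, 30 principal components and 15 nearest neighbours, with leidenalg 0.10.2 at resolution 0.5. A cluster was named after a cell type when at least 3 of that type's markers stood among its 10 top genes by fold. The markers were fixed before the data were examined, but this count was set after the clusters had been seen. UMIs were summed per library over the cells outside clusters named as another type than tumour.

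CPM values, the UMIs of a gene divided by all UMIs of the sum on the usual CPM scale, were computed per library, and log2 ratios of aPD-1 over IgG carried a pseudocount of 1 CPM, which understates the difference of low genes. Ratios are given without a pseudocount, with an exact conditional binomial 95% interval. Levels carry exact Poisson intervals where given, and shares of cells exact Clopper-Pearson intervals. All intervals cover counting error only. With 1 library per group no test was possible, cells are not replicates, and no p-value was computed. A gene was counted as higher or lower when its mean was at least 10 CPM, its ratio was at least 2-fold and its interval lay beyond 1.5-fold. The genes named are the up to 12 highest and 12 lowest of those, leaving out ribosomal, mitochondrial, haemoglobin and unnamed gene models; up to 4 extreme members of each gene list; and a set fixed in advance around Snai1, Ly6a, Birc2 and Birc3. Some genes taken by this rule are not reported here. Other genes are named only with the cluster or cell type they mark, or as chosen after their values were seen.

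For 27 pathway lists the median log2 ratio of the members of at least 10 CPM was set against 10000 random lists of the same size matched on expression in 20 bins. A list was said to stand apart when it lay outside the central 95% of them, which describes these 2 libraries and not the treatments. Lists of under 5 such members were not placed. Of the 740 listed symbols, 6 did not match the gene names in the matrices and were not used here. Shares of cells with a UMI and cell cycle phases were computed after thinning each cell to 2000 UMIs without replacement, leaving out shallower cells. Lists were recomputed within every cluster of at least 100 cells of each library. Transcript length, GC content and gene coordinates were taken from GENCODE M21 on GRCm38, the assembly also called mm10, by gene identifier. This annotation may differ from the release behind the matrices, and 28416 of the 28692 identifiers had coordinates in it. Near-identical genes, such as Hspa1a with Hspa1b, Tgtp1 with Tgtp2, the histone and ribosomal protein families and the H2 genes, can share reads in ways these counts do not show.

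The steps were tested on simulated counts drawn at the depths of this comparison over 6949 genes. All 50 genes simulated at 3-fold higher were counted, as were the 40 of 50 genes simulated at 3-fold lower that stayed above the 10 CPM minimum. None of the 50 genes at 1.5-fold and none of 6740 unaltered genes was counted. Apart from the changes put in, both libraries were drawn from 1 pooled profile with counting error only. The simulation therefore cannot tell how many genes would be counted between 2 libraries of the same treatment. Of 400 random lists, 6.25% lay outside the central 95%, and a list shifted by −0.30 was recovered at −0.30. The alternatives tried were other UMI and mitochondrial limits, cell calling rules, scalings, pseudocounts, expression minimums, cell weights, cell subsets, a free RNA correction at an assumed share of 5% with the profile of aPD-1 barcodes of 10 to 100 UMIs, thinning depths and clusterings. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.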

Results

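Transcripts of single cells were counted in 1 library of MC38 tumour spheroid cells kept for 6 days with control IgG and 1 library kept with aPD-1. The series describes its aim as profiling the tumour cells that remain after PD-1 blockade. The IgG library held 52720076 UMIs and the aPD-1 library 68385785. After filtering, 2461 IgG cells with a median of 19261 UMIs and 3888 genes were kept, beside 3365 aPD-1 cells with a median of 16549 UMIs and 3436 genes. The median mitochondrial share was 2.85% in IgG and 3.60% in aPD-1. Before the mitochondrial filter the order was the other way: 35.1% of IgG barcodes of at least 500 UMIs had over 10% mitochondrial UMIs, against 16.9% in aPD-1. There was no replicate of either treatment, so each difference below is one between 2 libraries, and treatment cannot be separated from sorting, loading or cell calling.

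The first question was which cells the sort had left. The cells fell into 10 clusters. Cluster 7 was macrophage or monocyte-like, with Fcer1g, C1qa, C1qb, Tyrobp and Lyz2 among its top genes, and held 125 IgG cells, 5.08% of that library (interval 4.25 to 6.02%). It held 0 of 3365 aPD-1 cells (upper bound 0.110%). The median of these cells was 1268 UMIs, under the floor of 4592 UMIs used for the aPD-1 library. With 1000 UMIs asked of both libraries instead, an alternative added after seeing the data, 4 of 3527 aPD-1 cells (0.113%) were macrophage-like. Cluster 9 was endothelial-like, with Plvap, Emcn and Esam among its top genes, and held 26 IgG cells (1.06%, interval 0.691 to 1.54%) and 4 aPD-1 cells (0.119%, interval 0.0324 to 0.304%). No cluster met the naming rule for T, NK or B cells, dendritic cells, neutrophils, mast cells, pericytes, erythroid cells or fibroblasts. Cd3e, a subunit of the T cell receptor complex, had 0 UMIs in the summed cells of both libraries.

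The other clusters carried no type name, because the epithelial genes chosen as tumour markers were close to 0 in both libraries. None of 18 such markers reached 10 CPM. Krt8, a keratin of simple epithelia, had 7 UMIs in IgG and 3 in aPD-1, Epcam had 1 and 0, and Krt18 had none in either. The cells expressed mesenchymal genes instead, with Vim at 1937 CPM in IgG and 1730 CPM in aPD-1. In the same order, fibroblast markers were at 463 and 326 CPM (Dcn), 298 and 186 CPM (Col3a1), 224 and 178 CPM (Col6a3), 133 and 83.9 CPM (Col1a1), 44.5 and 45.6 CPM (Fbn1), 37.8 and 30.8 CPM (Pdgfrb) and 32.7 and 25.3 CPM (Pdgfra). Others of the same list were low: Col1a2, an abundant collagen transcript of fibroblasts, stayed at 2.15 and 1.71 CPM, and Thy1 at 1 UMI in each library. The identity of these cells as tumour cells rests on the sort described in the labels. The sums below are over 2310 IgG cells with 49410126 UMIs and 3361 aPD-1 cells with 61456423 UMIs.

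The cells outside the named types differed by cell cycle, hypoxia and interferon genes. Clusters 1 and 6 led in G2/M genes (Cenpa, Cdc20, Ccnb1), cluster 2 in S phase and histone genes (Hist1h1b, Top2a), cluster 3 in hypoxia genes (Ero1l, Bnip3, Slc2a1) and cluster 5 in type I interferon genes (Mx1, Ifit1, Rsad2). Cluster 0 led in the TGF-beta list. Cluster 8, of 72 IgG and 9 aPD-1 cells, had Gpihbp1 and Igfbp7 among its top genes, as did the endothelial-like cluster 9. It met no naming rule and stayed in the sums. Cluster 4 had Gsn, Lbp, Dcn and Col3a1 among its top genes and led in the MHC class I list. It held 2 fibroblast markers among its top 10 genes, under the 3 the naming rule asks for, and 17.0% of IgG and 5.41% of aPD-1 cells. To compare shares, cells were clustered again without the genes that differed between the libraries, an alternative chosen after seeing the data. The cluster led by Gsn and Lbp then held 402 IgG cells (16.3%, interval 14.9 to 17.9%) and 190 aPD-1 cells (5.65%, interval 4.89 to 6.48%), and met the fibroblast naming rule. The hypoxia cluster held 11.5% of IgG cells (interval 10.3 to 12.8%) and 19.3% of aPD-1 cells (interval 17.9 to 20.6%). The type I interferon cluster held 4.35% (interval 3.58 to 5.23%) and 5.88% (interval 5.11 to 6.73%), intervals that overlap, as they did in 3 of 4 clusterings. In the clustering without cell cycle lists they did not, at 4.39% (interval 3.61 to 5.27%) of IgG and 6.69% (interval 5.87 to 7.58%) of aPD-1 cells. The share meeting the fibroblast naming rule also depended on the clustering. It was 15.5% of IgG and 4.10% of aPD-1 cells without cell cycle lists. At resolution 1.0 it was 5.24% (interval 4.39 to 6.20%) and 5.02% (interval 4.31 to 5.82%), intervals that overlap, and whether these are the same cells was not examined.

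The main comparison asked which genes differed between the cells left with aPD-1 and those left with IgG. Most did not differ by much: 97.2% of 6961 genes of at least 10 CPM lay within 1.5-fold. By the size rule 5 genes were higher and 19 lower in the aPD-1 library. Il1rl1, the receptor for interleukin-33, had the highest ratio, at 19.0 CPM in aPD-1 and 6.01 CPM in IgG (3.16-fold, interval 2.78 to 3.60). Also higher were Hmga2, a chromatin protein of embryonic and tumour cells (2.20-fold, interval 2.07 to 2.34), Mical2, an enzyme that oxidises actin (2.12-fold, interval 1.89 to 2.37), and Hist1h1b, a linker histone (2.08-fold, interval 1.93 to 2.25). The lowest ratio was that of Hes1, a transcriptional repressor downstream of Notch, at 38.1 CPM in aPD-1 and 134 CPM in IgG (ratio 0.285, interval 0.272 to 0.299).

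Below Hes1 came the growth factor Ptn (ratio 0.310), the matrix protein gene Dpt (0.355), the nuclear receptor gene Rorb (0.357), the lipopolysaccharide-binding protein gene Lbp (0.367) and the transcription factor gene Spib (0.382). The rest of the 12 lowest were Gsn, the actin-severing gelsolin (0.403), Hspa1b, an inducible heat shock protein (0.408), Rac2 (0.417), Jup (0.425), Entpd2 (0.427) and Id1, an inhibitor of DNA binding (0.460). Hes1 lies on chromosome 16 at 30064384 to 30067796 and Il1rl1 on chromosome 1 at 40429570 to 40465415 (GRCm38), both annotated as protein-coding. In direction, most of these differences were not those of cluster shares alone, but sign counts do not show how much of their size is. Gsn and Lbp were the top genes of cluster 4, which held 17.0% of IgG and 5.41% of aPD-1 cells. Over the alternative settings their log2 ratios weakened to as little as −0.82 and −0.71, and Lbp was at 1.31 in 1 cluster. Mical2 (0.77), Hist1h1b (0.83), Jup (−0.85), Entpd2 (−0.87) and Rac2 (−0.93) also fell short of 2-fold in their weakest setting. Hist1h1b was a top gene of cluster 2, which held 7.15% of IgG and 17.4% of aPD-1 cells. Within the 7 clusters of at least 100 cells of each library, Il1rl1, Hmga2, Mical2 and Hist1h1b were higher in 7 of 7. In their weakest clusters the log2 ratios were 0.06 (Hmga2), 0.10 (Mical2), 0.13 (Il1rl1) and 0.15 (Hist1h1b). Hes1, Ptn, Dpt, Rorb, Spib, Gsn, Hspa1b, Entpd2, Jup and Id1 were lower in 7 of 7, and Lbp and Rac2 in 6 of 7. In their weakest clusters Spib was at a log2 ratio of −0.04 and Dpt at −0.10, where cluster medians of all genes ran from −0.10 to −0.03. The median log2 ratio of all genes was −0.10, and ribosomal protein genes took 34.5% of UMIs in IgG and 38.2% in aPD-1. With that median set to 0, 6 genes were higher and 13 lower.

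**Figure D1:**
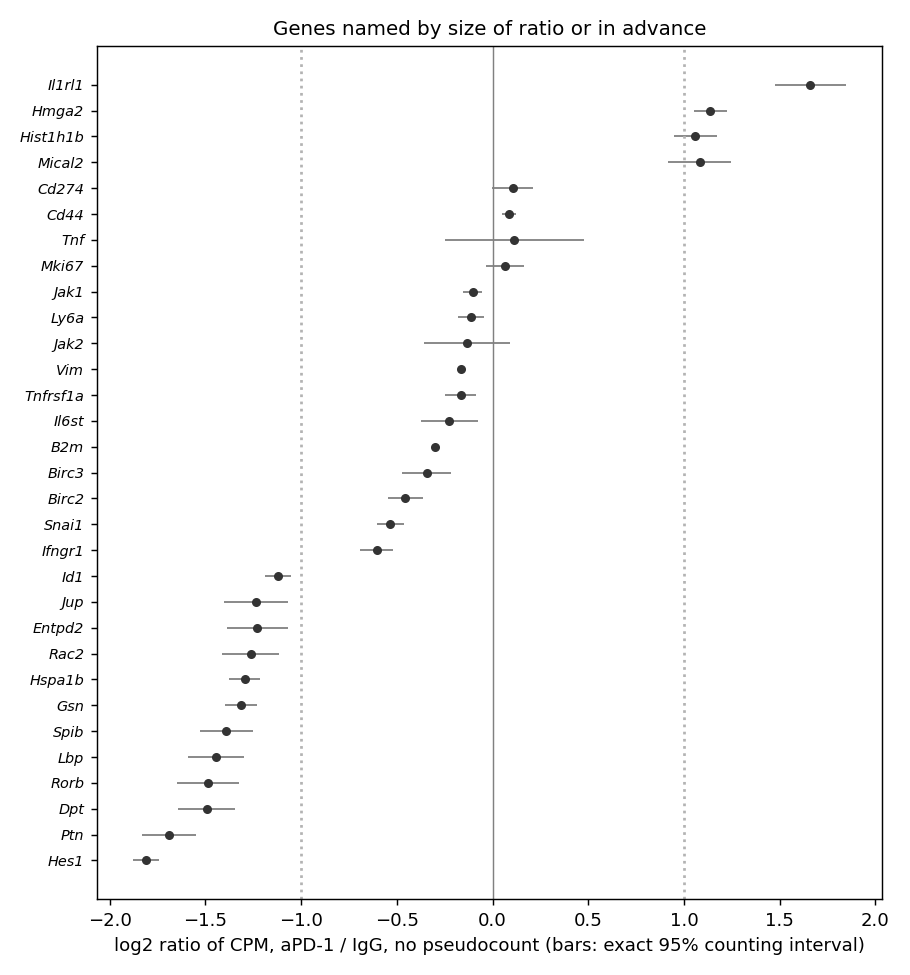
Log2 ratio of CPM, aPD-1 over IgG (horizontal axis), of genes named by the size of their ratio and of genes fixed in advance, each named in the text and with over 100 UMIs in both libraries together (vertical axis). Points are the ratio of 1 library to the other without a pseudocount, bars are exact 95% counting intervals, and dotted lines mark 2-fold; Il1rl1 is highest at 3.16-fold and Hes1 lowest at a ratio of 0.285.

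A second question concerned genes tied to residual cells after PD-1 blockade, which the group behind the series has described as positive for Snai1 and for Sca-1, the product of Ly6a. Snai1, a transcription factor of epithelial to mesenchymal transition, was lower in the aPD-1 library, at 48.5 CPM (interval 46.8 to 50.3) against 70.2 CPM (interval 67.9 to 72.6). It was lower in 7 of 7 clusters, in 3 of them with counting intervals that overlap, and in cluster 6 the log2 ratio of −0.08 was no lower than the median of −0.09 for all genes there. Ly6a was at 59.2 CPM in aPD-1 and 64.0 CPM in IgG (ratio 0.925, interval 0.882 to 0.971), a log2 ratio of −0.11 beside a median of −0.10 for all genes, which turned to 0.02 with every cell weighted equally and to 0.06 with a UMI floor of 500. Within clusters Ly6a went both ways, higher in 4, in 2 of them with counting intervals that overlap, and lower in 3. In cluster 4 it was at 188 CPM in aPD-1 (interval 174 to 203) and 116 CPM in IgG (interval 110 to 123). In cluster 1 it was at 31.4 CPM (interval 28.7 to 34.3) and 41.3 CPM (interval 37.7 to 45.2). The apoptosis inhibitor genes Birc2, at 30.9 and 42.4 CPM, and Birc3, at 16.1 and 20.4 CPM, were lower in the aPD-1 library, in 6 and 7 of 7 clusters. Lower here means under a ratio of 1, and only 32.9% of all 6961 genes lay above 1 in the sums. In their weakest clusters Birc2 was at a log2 ratio of 0.03 and Birc3 at −0.03, where cluster medians of all genes ran from −0.10 to −0.03. Il6 had 21 UMIs in aPD-1 and 11 in IgG, a ratio of 1.53 whose interval (0.707 to 3.53) includes 1. Tnf was at 2.47 and 2.29 CPM, with a ratio interval of 0.842 to 1.39.

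At 2000 UMIs per cell, Snai1 was detected in 13.7% of 2249 IgG cells (interval 12.3 to 15.1%) and 10.4% of 3361 aPD-1 cells (interval 9.43 to 11.5%). Ly6a was detected in 9.92% (interval 8.71 to 11.2%) and 10.1% (interval 9.06 to 11.1%), a difference not detectable at this depth. Both transcripts were detected together in 1.65% of IgG cells (interval 1.16 to 2.26%) and 1.07% of aPD-1 cells (interval 0.751 to 1.48%), where independent detection would give 1.35% and 1.05%. Thinning left out 61 IgG cells and 0 aPD-1 cells. Without thinning Snai1 was detected in 58.6% of IgG and 48.6% of aPD-1 cells, Ly6a in 38.1% and 35.5%, and both in 25.5% and 19.0%. The macrophage-like IgG cells, which should lack Snai1, had it in 0 of 125 cells (upper bound 2.91%) at a median of 1268 UMIs. The cells outside the named types had medians of at least 12857 UMIs in each of the 7 clusters of at least 100 cells of each library. Cluster 8, also outside the named types, had a median of 1837 UMIs in its 72 IgG cells. The deeper endothelial-like IgG cells had Snai1 in 26.9% of 26 cells (interval 11.6 to 47.8%) at a median of 11368 UMIs. The 0 of the shallow macrophage-like cells therefore sets no limit on background in deeper cells. No type lacking Ly6a was at hand, as 66.4% of macrophage-like and 100% of endothelial-like IgG cells had it.

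Antigen presentation genes of MHC class I were lower in the aPD-1 library as a list. The median log2 ratio of 16 members was −0.34, at percentile 0.03 of the random lists, and 15 of 16 lay below the median of all genes. Tap2, a subunit of the peptide transporter, was at 42.8 CPM in aPD-1 and 69.1 CPM in IgG, the chaperone Pdia3 at 140 and 209 CPM, and B2m, the shared light chain, at 2134 and 2632 CPM. H2-T22, a non-classical class I gene, went the other way, at 277 and 233 CPM. The list stood apart in 3 of 7 clusters, and in cluster 4, which leads in these genes and held a smaller share of aPD-1 cells, it lay 0.10 above the median of all genes. The count depends on the clustering: the list stood apart as lower in 2 of 7 clusters without the genes that differed, in 2 of 6 without interferon and MHC lists and in 0 of 6 without cell cycle lists.

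The interferon-gamma response list did not go with MHC class I. Its 30 members had a median of −0.04, at percentile 83.2, inside the random range. Socs1, a feedback inhibitor of cytokine signalling, was at 78.8 CPM in aPD-1 and 48.0 CPM in IgG, and the guanylate-binding protein gene Gbp4 at 28.7 CPM in aPD-1, a log2 ratio of 0.50; both were higher in 7 of 7 clusters. The chemokine gene Cxcl9 was at 60.8 and 89.9 CPM and Tgtp2 at 9.08 and 13.5 CPM. Within clusters this list stood apart as higher in 5 of 7 and lower in none, and under the other 3 clusterings as higher in 4 of 7, 3 of 6 and 4 of 6. Without the cluster rich in Gsn, Lbp and Dcn, a setting added after seeing the data, its median was 0.07, at percentile 99.91. Among the signalling genes fixed in advance, Ifngr1, a subunit of the interferon-gamma receptor, was at 32.8 CPM in aPD-1 and 49.9 CPM in IgG. Jak1 was at 120 and 129 CPM and Jak2 at 5.70 and 6.25 CPM. Cd274, which encodes PD-L1, was at 27.8 and 25.8 CPM (log2 ratio 0.10), with an interval that includes a ratio of 1. The type I interferon list had a median of −0.11 (26 members, percentile 40.0), with Oas3 at 13.3 and 9.47 CPM and Ifi27l2a at 200 and 317 CPM. Within clusters the MHC class II list stood apart as higher in 4 of the 6 with enough members, by 0.39 to 0.41, and lay at −0.27 in cluster 6, inside the random range. Under the other clusterings this held for 3 of 5, 2 of 5 and 3 of 4 such clusters. In the sums it had a median of 0.00 (6 members, percentile 87.3), which turned to −0.61 when the macrophage-like and endothelial-like cells were included.

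Cholesterol synthesis genes formed the lowest of the lists with at least 5 members of at least 10 CPM. All 20 members lay below the median of all genes, with a list median of −0.46 at percentile 0 of the random lists. Dhcr7, the last enzyme of the pathway, was at 18.2 CPM in aPD-1 and 31.6 CPM in IgG, and the demethylase Cyp51 at 119 and 197 CPM. The list stood apart as lower in 6 of 7 clusters, all but the type I interferon cluster. Without the genes that differed this held for 6 of 7 clusters and without cell cycle lists for 4 of 6. Without interferon and MHC lists it stood lower in 5 of 6 and higher, by 0.23, in the other. Immediate early and dissociation genes had a median of −0.42 (19 members, percentile 0) and stood apart as lower in 7 of 7 clusters. Under the other clusterings, in the same order as for cholesterol, this held for 7 of 7, 5 of 6 and 6 of 6 clusters. Egr2 was at 25.1 and 43.7 CPM, whereas Ier3 was at 321 and 244 CPM. Heat shock chaperones had a median of −0.34 (13 members, percentile 0.025), lower in 6 of 7 clusters and in 4 of 7, 4 of 6 and 4 of 6 under the other clusterings, with Dnaja1 at 237 and 385 CPM and Hspe1 at 1688 and 1518 CPM. These last 2 lists share members such as Hspa1b and respond to tissue handling. Glycolysis genes had a median of −0.24 (16 members, percentile 1.49), with Hk2 at 138 and 199 CPM and Gapdh at 2787 and 2788 CPM, but without the cluster rich in Gsn, Lbp and Dcn this list was inside the random range, at percentile 15.5. Cytoplasmic ribosomal protein genes were the list higher in the aPD-1 library, with a median of 0.25 (36 members, percentile 100), in 7 of 7 clusters. Rps2 was at 10012 and 7160 CPM and Rpl37 at 7183 and 8657 CPM.

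**Figure D2:**
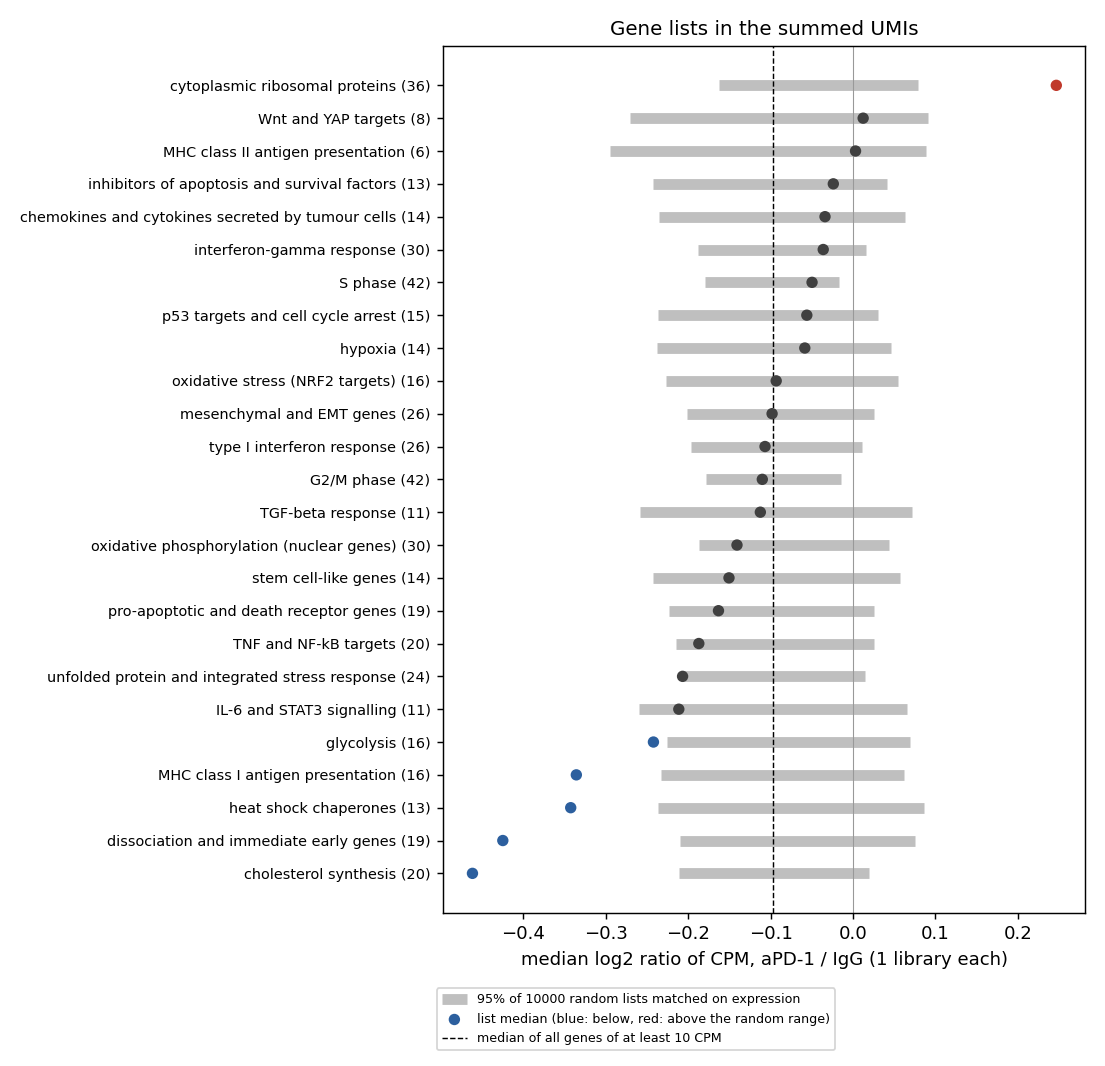
Median log2 ratio of CPM, aPD-1 over IgG (horizontal axis), of each gene list with at least 5 members of at least 10 CPM (vertical axis, number of members in brackets). Grey bars span the central 95% of 10000 random lists matched on expression, and the dashed line is the median of all genes; 5 lists lie below their bar (blue) and 1, the ribosomal proteins, above it (red).

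**Figure D3:**
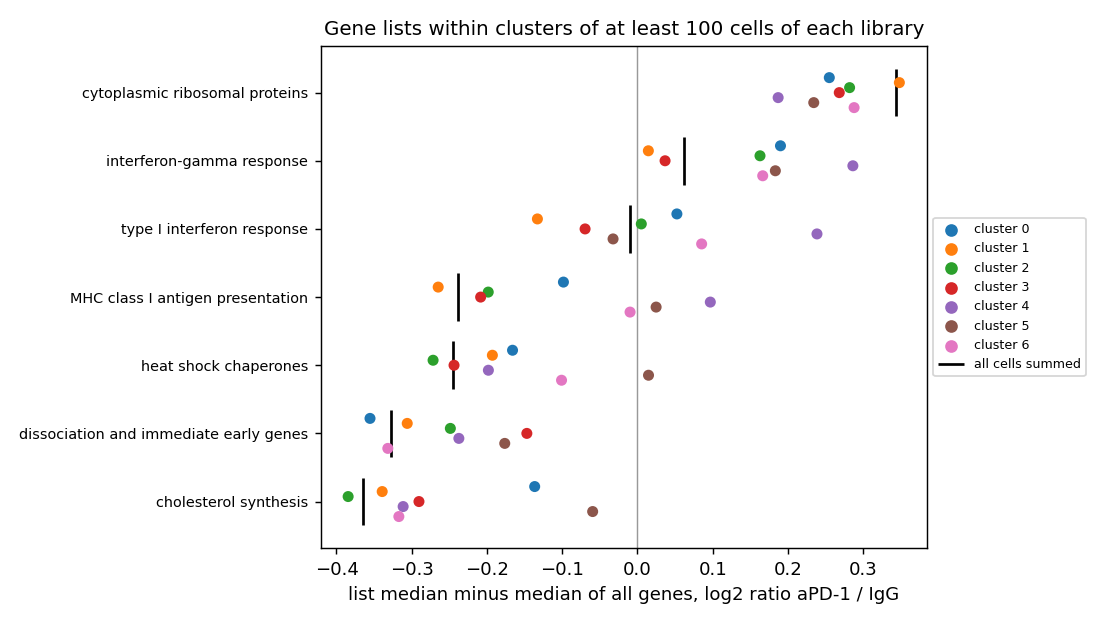
List median minus the median of all genes, as log2 ratio aPD-1 over IgG (horizontal axis), for 7 gene lists (vertical axis) within each of the 7 clusters of at least 100 cells of each library (coloured points) and in all cells summed (black lines). Immediate early genes lie below 0 and ribosomal proteins above 0 in 7 of 7 clusters, while MHC class I lies on both sides.

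The other lists lay inside the random range in the sums. The unfolded protein list was at its edge (median −0.21, 24 members, percentile 2.64) and stood apart as lower within 5 of 7 clusters, by up to −0.25, and within 4 under each of the other 3 clusterings, with Hspa5 at 272 CPM in aPD-1 and 430 CPM in IgG and the stress-induced factor gene Ddit3 at 122 and 89.5 CPM. TNF and NF-kB targets had a median of −0.19 (percentile 6.36), with Tnfaip2 at 83.9 and 149 CPM and Traf1 at 55.0 and 40.2 CPM. The IL-6 and STAT3 list had a median of −0.21 (percentile 8.62), with Lif at 23.9 and 17.3 CPM and Il6st at 12.4 and 14.5 CPM. Inhibitors of apoptosis had a median of −0.02 (percentile 82.8) and pro-apoptotic genes −0.16 (percentile 13.7), with the death receptor gene Fas at 15.4 and 26.1 CPM and Tnfrsf1a at 44.3 and 49.7 CPM. Mesenchymal genes had a median of −0.10 (percentile 44.1), with S100a4 at 439 and 735 CPM and Inhba at 25.4 and 16.6 CPM. Stem cell-like genes were at −0.15 (percentile 23.8), with Sox2 at 36.2 and 23.9 CPM, Clu at 20.3 and 41.2 CPM and Cd44 at 235 and 222 CPM. The p53 and arrest list was at −0.06 (percentile 73.6), with the kinase inhibitor gene Cdkn1a at 85.2 and 54.8 CPM. Secreted chemokines and cytokines were at −0.03 (percentile 74.5), with Il11 at 24.0 and 14.2 CPM and Il33 at 13.5 and 23.5 CPM. NRF2 targets were at −0.09 (percentile 44.9), with the ferritin gene Ftl1 at 3210 and 2376 CPM. The hypoxia list was at −0.06 (percentile 70.3), the TGF-beta list at −0.11 (percentile 41.8), Wnt and YAP targets at 0.01 (percentile 86.6) and nuclear oxidative phosphorylation genes at −0.14 (percentile 13.3). Only 2 epithelial genes, Jup and Tjp1, and 4 ligands of inhibitory receptors reached 10 CPM, with medians of −0.49 and −0.11 that were not placed.

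Cell cycle genes differed little in the sums. The S phase list had a median of −0.05 (42 members, percentile 86.8) and the G2/M list −0.11 (42 members, percentile 33.8). Within clusters they stood apart in both directions. S phase was 0.45 above the median of all genes in cluster 5, 0.30 above in cluster 4 and 0.14 above in cluster 0, but at −0.29 in cluster 2 and −0.16 in cluster 6. G2/M was at −0.32 in cluster 1, −0.11 in cluster 2 and 0.24 in cluster 5. Clusters 1, 2 and 6 are led by these same genes, so ratios inside them depend on where the clusters were cut. In the clustering without cell cycle lists, both lists still went both ways. Each stood apart as lower in 3 of 6 clusters and as higher in 1. Mki67, a proliferation marker, was at 31.5 CPM in aPD-1 and 30.2 CPM in IgG, with a ratio interval of 0.977 to 1.12. Top2a was at 118 and 90.6 CPM, and Cdc20 at 41.1 and 63.2 CPM. At 2000 UMIs per cell, 57.7% of IgG cells (interval 55.6 to 59.7%) and 55.1% of aPD-1 cells (interval 53.4 to 56.8%) were called G1. The S phase shares were 10.2% (interval 8.96 to 11.5%) and 11.3% (interval 10.3 to 12.5%), and the G2/M shares 32.1% (interval 30.2 to 34.1%) and 33.6% (interval 32.0 to 35.2%). The intervals of the 2 libraries overlap in each phase at this depth. At 4000 UMIs per cell they did not for G1 (56.5% and 50.9%) or S phase (12.5% and 15.5%).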

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

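Of the tests in this part, those on macrophage-like cells, on transcript length and GC content, on interferon-gamma signalling, on fibroblasts and on the cluster rich in Gsn, Lbp and Dcn were chosen or rest on settings added after results had been seen, and only that on cluster shares was fixed before.

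Several signals lay in cells and barcodes that the sums of the report left out, above what a count of 0 would allow. Alternative settings took in the macrophage-like and endothelial-like cells, but only a part of the barcodes under 1000 UMIs. With a UMI floor of 500, at least 500 genes were still asked, and 2525 IgG cells were kept beside 2461 in the main result. In barcodes of at least 500 but under 1000 UMIs, with at most 10% mitochondrial UMIs, C1qa, a complement gene of macrophages, was at 1950 CPM in IgG (489 UMIs in 353 barcodes) and 923 CPM in aPD-1 (105 UMIs in 167 barcodes), against 1.03 and 0.244 CPM in the summed cells. The haemoglobin gene Hbb-bs was at 2624 CPM in such IgG barcodes (658 UMIs). Macrophage-like cells made up 5.08% and endothelial-like cells 1.06% of the IgG cells, and both were left out of the sums.

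The first pattern weighed is the presence of macrophage-like cells in IgG and almost none in aPD-1. Cell calling that differed between the libraries is argued against, because with the same filters in both the share in aPD-1 had an upper bound of 0.290%, below the lower bound of 4.28% in IgG. The efficiency of the tumour cell sort could not be told from treatment, as the 4 macrophage-like aPD-1 cells found with the same filters come from 1 sort and 1 treatment. Free RNA of 89441 aPD-1 barcodes of 10 to 100 UMIs held C1qa at 37.2 CPM, so macrophage transcripts were present in that sample. That aPD-1 left fewer macrophages in the cultures is therefore a hypothesis that these 2 libraries leave open.

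The second pattern is the lower MHC class I antigen presentation list in the aPD-1 library. Different shares of the clusters could contribute, since the list lay over 0.1 below the median of all genes in only 3 of 7 clusters. The share of the cluster rich in Gsn, Lbp and Dcn alone is not enough, as without that cluster the list median was −0.24 at percentile 0.73 of the random lists, and transcript length and GC content are argued against by a percentile of at most 0.12 after their trends were removed. Fibroblasts left by the sort stay open: Col1a2, Lum, Postn and Thy1 reached at most 2.49 CPM in the cluster rich in Gsn, Lbp and Dcn. However, 4 listed fibroblast markers of at least 10 CPM were highest there, Dcn (998 CPM), Col3a1 (605 CPM), Col1a1 (245 CPM) and Dpt (49.8 CPM), and other clusterings named it fibroblast. The biological hypothesis of less interferon-gamma signalling with aPD-1 stays open. For all cells summed the response list was at percentile 83.2, with 13 of 30 members over 0.1 above the median of all genes. It stood higher in 5 of 7 clusters and lower in none, and higher in the cells outside that cluster, at percentile 99.91. However, that cluster led in MHC class I genes, had Cxcl9 among its top genes and held 17.0% of IgG and 5.41% of aPD-1 cells. If less signalling moved cells out of it, leaving it out or comparing within clusters would hide the difference. These values therefore describe the cells compared and cannot decide the question.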

How the results depend on the processing

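No paired analysis was possible because there was 1 library per group and no replicate numbers. Each result was computed again under 14 alternatives fixed before the data were examined and 5 added after seeing them, and cell types and clusters also under other clusterings. The 17 genes taken by size kept their direction in 323 of 323 values. This says little by itself, as the expression minimums leave a ratio as it was and most settings reuse the same UMIs. Sizes did change: the log2 ratio came to −0.71 for Lbp and −0.82 for Gsn at the weakest, short of 2-fold. Mical2 (0.77), Hist1h1b (0.83), Jup (−0.85), Entpd2 (−0.87) and Rac2 (−0.93) also fell short of 2-fold at their weakest. The MHC class I, cholesterol, immediate early, heat shock and ribosomal lists stayed outside the random range under all the alternatives. Of 473 list values, 451 kept their place inside, above or below the random range. Snai1 stayed lower, with a log2 ratio of −0.57 to −0.43, while Ly6a ranged from −0.43 to 0.06. Leaving out doublet removal, also fixed beforehand, was not run separately, as no doublet was removed in the main result. Where a cause is not named below, the cause was not tested.

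By the size rule, 27 genes were higher and 89 lower among genes of at least 1 CPM, 0 and 3 among genes of at least 50 CPM (other genes enter or leave), and 30 were lower with all cells, which adds the macrophage-like cells. With the median of all genes set to 0 the counts were 6 and 13, beside 5 and 19.

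With a UMI floor of 500 the cluster rich in Gsn, Lbp and Dcn met the fibroblast naming and left the sums; medians were 0.0729 for interferon-gamma (now outside), −0.23 for G2/M (outside), −0.15 for glycolysis (inside) and −0.20 for the unfolded protein list (outside). Without that cluster they were 0.0696, −0.22, −0.14 and −0.21 in the same order. With all cells, macrophage-like ones included, MHC class II turned to −0.61. With at most 5% mitochondrial UMIs, TNF and NF-kB was at −0.21 and S phase at 0.00281 (both outside), and glycolysis at −0.20 (inside). With genes of at least 50 CPM, IL-6 and STAT3 was at −0.33 (outside) and glycolysis at −0.22 (inside). In cells called G1, pro-apoptotic genes were at −0.26, S phase at 0.10, G2/M at 0.0265 (turned) and the unfolded protein list at −0.23 (all outside); these cells are chosen by the S and G2/M genes. Without the 5% of cells with most UMIs, S phase was at −0.00893 (outside). The unfolded protein list was also outside at −0.21 with the order-of-magnitude floor in both libraries, −0.21 with genes of at least 1 CPM and −0.24 with cells weighted equally.

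Detection follows depth. Thinned to 1000 UMIs, Snai1 was detected in 6.88% of IgG and 5.44% of aPD-1 cells, Ly6a in 5.37% and 5.68%, and both in 0.260% and 0.268%; thinned to 4000, the shares were 24.3% and 18.4%, 16.1% and 15.9%, and 4.32% and 3.15%. With at most 20% mitochondrial UMIs Snai1 was detected in 12.1% of IgG cells, and with all cells Ly6a in 11.6%.

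In IgG the G1 share was 60.4% thinned to 1000 UMIs and 54.9% with at most 20% mitochondrial UMIs. The S share was 11.8% at 1000, 12.5% at 4000 and 12.7% with no thinning. The G2/M share was 27.8% at 1000, 29.7% with no thinning and 34.7% with at most 20% mitochondrial UMIs. In aPD-1 the G1 share was 59.2% at 1000, 50.9% at 4000, 52.9% with no thinning and 51.9% with at most 20% mitochondrial UMIs. S phase was 15.5% at 4000, 16.9% with no thinning and 12.6% with at most 20% mitochondrial UMIs, and G2/M 29.2% at 1000, 30.2% with no thinning and 35.5% with at most 20% mitochondrial UMIs.

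At resolution 0.2 there were 5 clusters. The macrophage-like share of IgG was 0% with the order-of-magnitude floor in both libraries, 6.61% with a UMI floor of 500, and 6.61% with 500 UMIs in both and no order-of-magnitude rule. In aPD-1 it was 0.113% with 1000 UMIs in both and 0.169% with 500 in both. No cluster met the endothelial naming rule at resolution 1.0 or without interferon and MHC lists, a named share of 0% in both libraries. Under the latter clustering an unnamed cluster with Plvap and Emcn among its top genes held 28 IgG and 4 aPD-1 cells. That 0% therefore comes from the naming rule. Whether such a cluster was there at resolution 1.0 was not examined.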

Other observations

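Of the tests in this part, those on transcript length and GC content and on shallow cells were chosen or rest on settings added after results had been seen, as were the genes and clusters described in the next 2 paragraphs.

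Some list members differed in the same direction in each of the 7 clusters although their lists lay inside the random range. Higher in the aPD-1 library were the cytokine gene Il11 at 24.0 CPM in aPD-1 and 14.2 CPM in IgG, Twist2, a mesenchymal transcription factor gene, at 76.1 and 54.6 CPM, and Fth1, the ferritin heavy chain, at 3777 and 2934 CPM. Inhba, Sox2, Lif, Traf1 and Ftl1 were likewise higher in 7 of 7 clusters. Lower in 7 of 7 clusters were Vcam1, an adhesion molecule gene, at 178 and 290 CPM, Tnfaip2 and S100a4. Id3, a partner of Id1 in the TGF-beta list, was at 68.0 and 121 CPM and lower in 6 of 7.

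Cell cycle clusters were also compared in the clustering without the genes that differed between the libraries. The cluster with Hist1h1b and Top2a among its top genes held 6.50% of IgG cells (interval 5.56 to 7.55%) and 10.7% of aPD-1 cells (interval 9.70 to 11.8%), and the cluster with Mybl2 and Uhrf1 9.79% and 21.9%, with intervals that do not overlap. The cluster with Rrm2, Tyms and Mcm7, which had the strongest S phase lead, went the other way, at 11.6% (interval 10.4 to 13.0%) and 6.54% (interval 5.73 to 7.43%). The G2/M cluster with Cenpe, Cdc20 and Tpx2 held 9.51% (interval 8.38 to 10.7%) and 6.39% (interval 5.59 to 7.27%), but this depended on the clustering. In the main one the cluster with these genes held 20.3% and 23.7%, with intervals that do not overlap. The other G2/M-led cluster there, cluster 6, stayed lower in aPD-1, at 6.10% and 3.42%. Without interferon and MHC lists the cluster with Cenpe, Cdc20 and Tpx2 held 25.3% and 24.5%. A cluster of 79 cells with a low UMI count, led by Gpihbp1 and Igfbp7, held 2.89% of IgG and 0.238% of aPD-1 cells. In the main clustering the IgG cells of the cluster led by these genes had a median of 1837 UMIs. That is under the floor of 4592 UMIs asked of aPD-1 cells alone, so this difference is set at least in part by the floors. Free RNA of the aPD-1 library held Snai1 at 39.3 CPM, Ly6a at 59.7 CPM and Dcn at 270 CPM, a level for Ly6a close to its 59.2 CPM in the summed cells.

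The last pattern weighed is the lower cholesterol synthesis list in the aPD-1 library. Different shares of clusters are argued against, as the list lay over 0.1 below the median of all genes in 6 of 7 clusters. Transcript length and GC content are argued against by a percentile of 0 among random lists after their trends were removed, and shallow cells by a percentile of 0 with the order-of-magnitude floor in both libraries. Free RNA stays open although the percentile was also 0 with it subtracted. The reason is that this correction assumed a share of 5% and a profile from aPD-1 barcodes alone. In aPD-1, C1qa lay below that share, at 37.2 CPM in those barcodes and 0.244 CPM in the summed cells, as did Lyz2, Fcer1g and Igfbp7. The haemoglobin genes Hbb-bs, at 8.69 and 5.17 CPM, and Hba-a1 lay above it. The IgG library has no such barcodes to measure the share. What the 2 libraries cannot tell is treatment from handling, and no biological explanation was tested.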
